A study of Homo sapiens with 4 samples.

How the data were processed

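RNA of 4 human cell samples was measured on 4 one-colour (Cy3) Agilent expression arrays of design 039494, 1 array per group: EB without alcohol, EB with alcohol, NPC without alcohol and NPC with alcohol. Groups, the dose of 100 mM and the exposure of 48 h were taken from the sample labels. Per the labels' protocols, RNA was extracted on columns with a DNase step, and 500 ng of total RNA was amplified and labelled from oligo-dT primers with Cy3. Oligo-dT priming favours the part of a transcript near its poly(A) tail, so a probe reads only the transcripts that contain its 60 bases. The labels state the same NPC maintenance medium for all samples, EB included.

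The deposited scanner files hold spot intensity on a linear scale, extracted with Agilent Feature Extraction version 11.5.1.1, per the file headers; the submitters' processing notes name the same software. The processed intensity in these deposited files is background-subtracted and detrended over the array surface, with substitute values for dim spots, per the file headers, and is not scaled between arrays. The deposited value table holds log2 values per gene name. Set against the scanner files, each of its columns equals the mean log2 processed signal of a gene name minus 1 constant per array (7.35, 7.31, 8.44 and 8.38 for the EB control, EB alcohol, NPC control and NPC alcohol arrays). This holds within 0.01 log2 for 90.6%, 90.7%, 91.8% and 92.0% of 36330 gene names. The rule behind the remaining names stays unknown; the values are not centred per gene. The column medians were -2.98, -2.96, -3.73 and -3.75. The table was used as an alternative only.

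Each array held 62976 spots, 4259 of them controls. Control spots and spots with an outlier flag (0.69%, 0.79%, 0.99% and 0.83% of the others, in the same order) were left out. The value of a probe is the mean over its remaining spots of log2 processed signal minus the array's 75th percentile over its 58717 non-control spots. A gene is represented by the probe with the highest mean over the 4 arrays; 36301 gene names were kept after 77 probes with every spot flagged on an array were left out. Differences were counted over genes well above background on both arrays, by the scanner software's own flag. A gene with that flag on 1 of 2 arrays has a bound: the bright array's value minus the higher of the dim value and the lowest signal well above background on the dim array. Array names of genes can be old. Of 36337 names, 20499 were matched by accession to the RefSeq gene table, 630 by symbol and 275 by synonym, and 14933 were not matched and keep the name of the array design; 18886 have a usable gene symbol. Coordinates are those of the probes in the scanner files (hg19 per the file headers). Exon and UTR positions of the probes were not determined here.

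The array number limits the precision: 1 array per group gives no estimate of the spread between cultures, so differences between 2 arrays are values with a rule of size (2-fold) and no p-value. The spread between spots was measured on 902 probes printed 10 times, whose median SD over the 10 spots was 0.053, 0.055, 0.041 and 0.041 log2. Fixed lists of genes, 36 in number, were summarised by the median difference of members well above background on both arrays. Its percentile was taken among 10000 random lists of the same size drawn from the same 20 bins of mean signal, as a description of these arrays. A response alike in both stages was tested with limma (version 3.58.1; lmFit and eBayes with trend) on the model of stage plus alcohol, over 21920 genes well above background on at least 2 of the 4 arrays, with Benjamini-Hochberg adjustment. Its 1 residual degree of freedom holds both noise and any difference in response between the stages, so its p-values measure only the spread between these arrays.

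The lists, the limma test, the alternatives below and the rule for named genes were fixed before the data were examined; the tests of explanations were chosen later. The rule named, per comparison, the 10 genes with the largest differences in each direction among genes with a symbol that were well above background on both arrays, brighter than the median such gene on the brighter array, and at least 0.5 log2 apart on the same side with normexp correction. It added the 3 largest bounds in each direction, 2 to 4 list members with the largest absolute difference, the 5 genes in each direction with the largest smaller response in both stages, the 5 in each direction with the largest difference in response, and genes past the limma threshold. Of the genes this rule picked, 2 are not reported here. The alternatives fixed with it were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, a median shift, the authors' value table, no filter and a stricter filter on dim genes, the mean over a gene's probes, outlier spots kept, rules of 1.5-fold and 3-fold, the alcohol arrays for the stage difference, and for limma no trend, a robust fit, no filter, no stage term, normexp and the authors' table. Chosen after seeing the data were a shift to the 274 spots of the spike-in RNAs, the removal of a lowess trend (fraction 0.3) on probe GC content, and the rule that every probe of a gene with 2 or more probes passes.

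The steps were tested on simulated data. For limma, 50 of the 21920 genes were changed at each of 4 sizes, with noise drawn from the model's own fitted prior. The fit recovered 34% of genes changed by 1 log2, 76% by 2, 92% by 3 and 94% by 4, and called 11 unchanged genes, and 1 gene when no change was simulated. An earlier simulation that took each gene's shrunken variance as its true noise called more unchanged genes, so these shares hold only where the noise follows the prior. Of 200 simulated lists of 25 unshifted genes, 6% in EB, 4.5% in NPC and 6% for the stages lay in the outer 2.5% of random lists on either side. Their differences were drawn independently for each gene, so variation shared by the members of a list was not simulated. Of lists shifted by 0.22 log2 in EB, 0.18 in NPC and 0.70 between the stages, 53.5%, 51% and 55% lay in the upper 2.5%. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.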

Results

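Gene expression was measured in human cells at 2 stages of neural differentiation, each with and without exposure to alcohol. The study asks how alcohol acts on human neural precursors at different stages of neurogenesis. The earlier stage is labelled EB, which usually stands for embryoid bodies, the aggregates that pluripotent stem cells form as they begin to differentiate; the labels give only the abbreviation. The later stage is labelled NPC, neural precursor cells. The cells derived from human embryonic stem cells, and the EB titles carry the tag H9, which is also the name of an embryonic stem cell line. Both NPC titles carry the tag CHIR, which the labels do not explain. Exposed cells received a compound labelled OH, which the series title calls alcohol, at 100 mM for 48 h.

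Each of the 4 groups (EB control, EB alcohol, NPC control and NPC alcohol) was measured on 1 array, so no value below has a replicate error and no p-value can be given for a difference between 2 arrays. The arrays were Agilent one-colour (Cy3) expression arrays with 60-base probes, from 1 slide and 1 scan date, holding 50599 probes for 36337 gene names. Spots well above background made up 57.4% of the EB control array, 58.2% of the EB alcohol array, 59.0% of the NPC control array and 59.2% of the NPC alcohol array, and 0 spots were saturated. The 75th percentile of the processed signal was 197 and 193 on the EB arrays and 479 and 476 on the NPC arrays. A total of 902 probes were printed 10 times on each array. Over these spots the difference between 2 arrays had a median SD of 0.08 log2 in EB and 0.06 log2 in NPC, and 0.17 and 0.12 log2 among the dimmer of these probes. This spread covers the printing and reading of spots within an array, and not the difference between cultures.

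Differences are given as log2 of one array over another after each array was set to its own 75th percentile, for genes well above background on both arrays unless a bound is stated. Where a gene was well above background on 1 of the 2 arrays, its fold is written as "at least", against the floor of the dim array. Gene lists were read as the median log2 difference of their measured members and its percentile among 10000 random lists of the same size and brightness. List medians are read against the median of all genes in that comparison, which was -0.02 for alcohol in EB, 0.00 for alcohol in NPC and -0.19 for NPC against EB. A list is said to stand apart where its median lies in the outer 2.5% of random lists on either side. With 36 lists per comparison, 1.8 would do so by chance alone if the members of a list varied independently. Random lists do not carry variation that the members of a list share. More than 1.8 lists could therefore stand apart between 2 cultures without alcohol. The medians and the numbers of members on either side hold for the 75th percentile scaling. With the arrays set to their spike-in spots, the median of all genes was -0.30 for alcohol in EB, +0.28 for alcohol in NPC and +1.17 for NPC against EB. This moves every list by the same amount. The percentiles do not depend on it or on the median shift. Both are among the alternatives counted below and could not change a percentile.

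In EB, the array of alcohol-exposed cells had higher signals for epithelial, hypoxia and immediate early genes and lower signals for replication, mitosis and cholesterol genes than the control array. The largest shift of a list was in surface ectoderm and epithelium, where 17 of 19 measured members were higher, with a median of +0.58 log2 (percentile 100). Its leading members were GATA2 (+1.13), a transcription factor of trophoblast and blood lineages, CLDN4 (+0.81), a tight junction protein, DSP (+0.79), a desmosome protein, and ELF3 (+0.68), an epithelial transcription factor. Of 34 hypoxia and glycolysis genes 31 were higher (median +0.28, percentile 100), led by the collagen cross-linking enzyme LOX (+0.94), NDRG1 (+0.86) and the mitochondrial adenylate kinase AK4 (+0.77). Of 25 immediate early genes 18 were higher (median +0.25, percentile 99.99), with EGR3 at +1.98, JUN at +0.87 and EGR4 at +0.67. In all, 12 of the 36 lists stood apart, 9 of them higher. Higher is meant here relative to all genes: on the spike-in scale 14 of 19 epithelial, 17 of 34 hypoxia and 12 of 25 immediate early genes lay above 0, with medians of +0.31, 0.00 and -0.03.

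Cell cycle and sterol lists lay on the lower side in EB with alcohol. Of 30 genes of the G1/S phase 26 were lower (median -0.23, percentile 0), among them the replication licensing factor CDC6 (-1.05), the ribonucleotide reductase subunit RRM2 (-0.71) and the DNA polymerase subunit POLE (-0.57, and -0.02 by its other probe), while CLSPN, a replication checkpoint adaptor, was at +0.76. Of 30 G2/M genes 24 were lower (median -0.17, percentile 0.07), with the cytokinesis regulator ECT2 at -0.40 and the spindle checkpoint kinase BUB1B at -0.36. Cholesterol biosynthesis had 19 of 25 members lower (median -0.17, percentile 0.15), led by the sterol desaturase SC5DL (-0.68), HSD17B7 (-0.67), and the mevalonate pathway enzymes MVD (-0.64) and IDI1 (-0.63).

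Other lists on the higher side in EB were neural crest, with 12 of 15 members higher (median +0.32, percentile 99.6; +0.17 with bounds), and forebrain patterning, with 9 of 12 (median +0.30, percentile 98.3, but 81.8 with the mean over probes). Neural crest was led by ALX1 (+1.35) and PRRX1 (-1.0), both transcription factors of craniofacial mesenchyme. The forebrain list was led by OTX1 (+1.09) and EOMES (-0.95). Cell adhesion and extracellular matrix had 22 of 28 members higher (median +0.19, percentile 99.97), with E-cadherin CDH1 at +0.92, fibronectin FN1 at +0.74 and tenascin TNC at +0.73. Imprinted genes had 16 of 24 higher (median +0.19, percentile 100), including the growth factor IGF2 (+0.66), with PLAGL1 at -0.60. Metallothioneins, which bind zinc and copper, had 9 of 11 higher (median +0.20, percentile 98.5, and 97.0 with a stricter filter, where they did not stand apart). Neural progenitor genes had 18 of 28 higher (median +0.10, percentile 98.2), with ZIC2 at +1.30 and HES6 at -0.62, but the list did not stand apart under 4 of 10 alternatives (percentile 94.9 at the lowest). On the spike-in scale 10 of 28 adhesion, 9 of 24 imprinted, 3 of 11 metallothionein and 7 of 28 neural progenitor genes lay above 0. On that scale these lists too were higher only relative to all genes. Which scale holds could not be determined with 1 array per group.

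Stress and lineage lists that did not stand apart in EB held single members with large differences. The p53 target median was at percentile 54.9, with the pro-apoptotic BAX at +1.02 and the cell cycle inhibitor CDKN1A at +0.75. The unfolded protein and integrated stress response list was at percentile 59.5, with DDIT4 at +1.1 and SDF2L1 at +0.92. Oxidative stress genes were at percentile 51.9, heat shock genes at 62.3 and alcohol and aldehyde metabolism at 37.7. The median of pluripotency genes was +0.02 (percentile 74.6), with POU5F1, a core pluripotency factor, at +1.29. Mesoderm genes were at percentile 92.7 and endoderm genes at 36.1. HAND1, a transcription factor of heart and extraembryonic mesoderm, was at +2.85, and the endoderm factor GATA6 at -1.48.

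**Figure D1:**
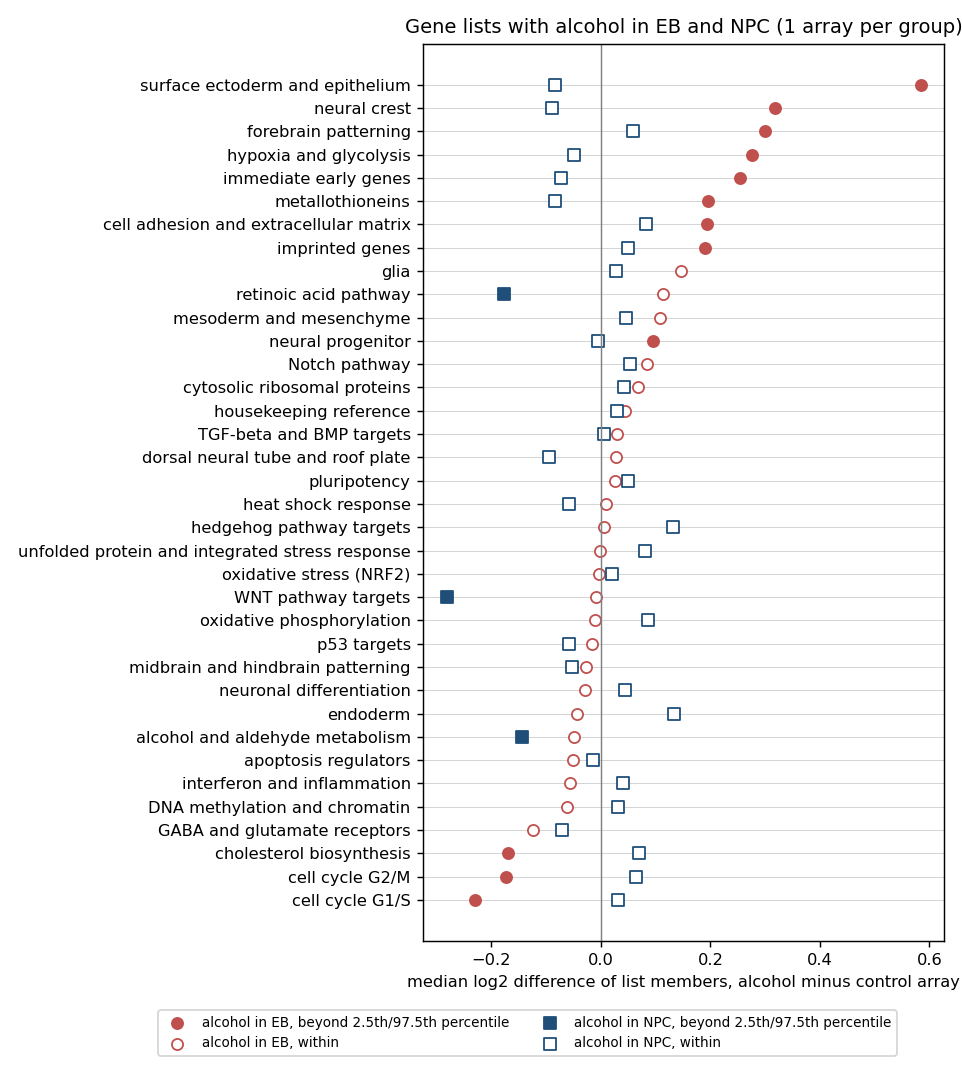
Median log2 difference between the alcohol and the control array (x axis) for the measured members of each of 36 gene lists (y axis), circles for EB and squares for NPC, 1 array per group. Filled marks lie in the outer 2.5% of random lists on either side, which holds for 12 lists in EB and 3 in NPC; surface ectoderm and epithelium stands highest in EB at +0.58 and WNT pathway targets lowest in NPC at -0.28.

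Of 19736 genes well above background on both EB arrays, 412 were at least 2-fold higher and 171 at least 2-fold lower with alcohol. The differences had an SD of 0.446 log2 across genes. The genes ranked here, bounds aside, have a symbol, are brighter than the median gene and stay at least 0.5 log2 apart with normexp background correction. By this rule the highest were ISCA1, an iron-sulfur cluster assembly factor (28.0-fold), IL1RAPL1, a synaptic membrane protein (17.1-fold), CLEC1A (11.2-fold), SIGLEC15 (8.59-fold) and RAP1GAP (7.59-fold). They were followed by the probe named for the small nucleolar RNA SNORD108 (7.23-fold), HAND1 (7.19-fold), the olfactory receptor OR52E8 (7.05-fold), the keratin KRT79 (7.03-fold) and the transporter subunit OSTBETA, now named SLC51B (6.62-fold). Labelling was from oligo-dT primers, and which transcripts are read by the probes named for small nucleolar RNAs, here and below, was not determined. The HAND1 probe lies on chromosome 5 at 153854793 to 153854852 and the KRT79 probe on chromosome 12 at 53215321 to 53215380 (hg19 per the file headers). Lower with alcohol were NSMCE1, a subunit of the SMC5/6 complex (31.3-fold), the cilium protein BBS7 (8.94-fold), SNORD26 (7.51-fold), PHYHIP (7.24-fold) and NDNL2, also of the SMC5/6 complex (6.27-fold). MMACHC, which processes vitamin B12, was 5.37-fold lower, CARD9 5.34-fold, the chitinase CHIT1 3.14-fold, LSM14B 2.73-fold and PCDHGA7 2.54-fold. The largest bounds were CASP14 at least 16.4-fold, TNMD at least 15.4-fold and OR13C2 at least 14.8-fold higher, and SLC6A19 at least 19.4-fold, IQCF6 at least 19.3-fold and TSPYL6 at least 16.7-fold lower.

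Single genes in EB rested mostly on 1 probe. ISCA1 had 2 other probes, both on the opposite side, and the other probes of NSMCE1 and MMACHC were each at -0.01. The 2 other probes of LSM14B averaged +0.64, and that of PCDHGA7 was at -0.42. Over the 70 genes at least 2-fold apart that had other probes well above background, 52.2% of 92 other probes lay on the same side. The share of higher genes among those at least 2-fold apart was 70.7%, against 56.2% in the authors' value table and 37.7% when arrays were set to their spike-in spots. With normexp background correction, which draws differences of dim genes toward 0, 187 genes were higher and 52 lower, and IL1RAPL1 was at 2.77, CLEC1A at 2.15, ALX1 at 0.83, OTX1 at 0.32, EGR3 at 1.1, CDC6 at -0.37 and GATA6 at -0.37.

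**Figure D2:**
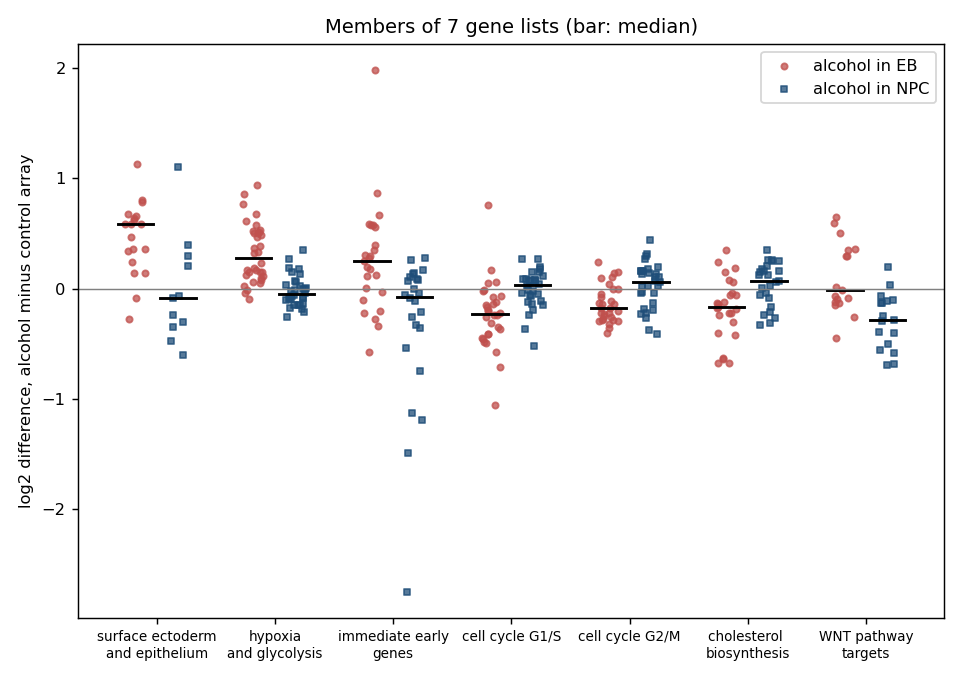
Log2 difference between the alcohol and the control array (y axis) for each measured member of 7 gene lists (x axis), circles for EB and squares for NPC; the bar is the median of the members. In EB 17 of 19 epithelial and 31 of 34 hypoxia genes lie above 0 and 26 of 30 G1/S genes below; in NPC 15 of 17 WNT targets lie below 0.

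In NPC, the alcohol array had lower signals for WNT pathway targets, and for several immediate early genes, than the control array. Of 17 measured WNT targets 15 were lower (median -0.28, percentile 0.01), and 9 of 17 on the spike-in scale, where the median was 0.00 against +0.28 for all genes. Whether either NPC culture held an added WNT activator is not given in the sources used here. They were led by SP8 (-0.69), a transcription factor whose other probe lay on the opposite side, by the WNT antagonist DKK1 (-0.68), by LGR5 (-0.58), a receptor that strengthens WNT signals, and by RNF43 (-0.56), a ligase that removes WNT receptors. Retinoic acid pathway genes had 13 of 19 members lower (median -0.18, percentile 0.13, but up to 13.9 without the filter or with a stricter one on dim genes; 14 of 19 higher on the spike-in scale), with the retinaldehyde dehydrogenase ALDH1A1 at -1.46, the receptor RARG at +1.04 and HOXB1 at -0.71. Alcohol and aldehyde metabolism, which shares ALDH1A1, had 11 of 19 lower (median -0.14, percentile 1.93), with the alcohol dehydrogenase ADH1C at -0.79 and ALDH3B1 at +0.52. It did not stand apart under 6 of 10 alternatives (percentile up to 53.9), and on the spike-in scale 14 of 19 were higher. These were the 3 lists of 36 that stood apart in the main analysis.

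Immediate early genes in NPC were split, with 14 of 24 lower and a median of -0.07 (percentile 14.4), but 4 members were at least 2-fold lower. These were ZFP36, whose protein promotes mRNA decay (-2.75), EGR1 (-1.49), FOS (-1.19) and JUNB (-1.12). None of the 12 lists that stood apart in EB did so in NPC. The median was -0.08 for surface ectoderm and epithelium (percentile 16.9), -0.05 for hypoxia and glycolysis (3.16), +0.03 for G1/S (51.7), +0.06 for G2/M (85.5) and +0.07 for cholesterol biosynthesis (84.7). Neuronal differentiation genes had a median of +0.04 (percentile 84.6), with GAD1, a GABA-synthesising enzyme, at +1.11 (-0.42 by its other probe). The p53 targets had a median of -0.06 (percentile 6.97), with the pro-apoptotic PMAIP1 at +0.99 and CDKN1A at -0.94. Among midbrain and hindbrain genes (percentile 19), EN2 was at -1.12.

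Of 20128 genes well above background on both NPC arrays, 150 were at least 2-fold higher and 265 at least 2-fold lower with alcohol, and the differences had an SD of 0.366 log2. Among genes picked by the rule given for EB, which leaves out some genes with larger differences, the highest were the phosphatase DUSP23 (3.36-fold), the keratin KRT18 (2.16-fold, and +1.54 log2 by its other probe) and the ubiquitin ligase subunit FBXO11 (2.08-fold). LINC00340, RBM27, BRWD1, PMAIP1, CCDC125, LARS and GOLGB1 lay between +0.97 and +1.01 log2. The lowest by the same rule were MLC1, a membrane protein of astrocytes (37.9-fold; chromosome 22 at 50497948 to 50498007), the growth factor FGF1 (-4.17 log2), ZNF736 (7.30-fold) and ZFP36 (6.72-fold; chromosome 19 at 39899758 to 39899817). They were followed by KCTD19 (3.94-fold), SFXN5 (3.62-fold), the centriole protein CEP120 (3.59-fold), RBAK-LOC389458 (3.55-fold), the mitochondrial pyrophosphatase PPA2 (3.19-fold) and HIF3A, of the hypoxia-inducible factor family (2.92-fold). The largest bounds were SLC35D3 at least 351-fold, LIM2 at least 15.1-fold and FOXP2 at least 11.4-fold higher by 1 probe (+0.22 log2 by its other probe), and CHSY3 at least 36.2-fold, S100Z at least 22.7-fold and MMP10 at least 22.2-fold lower. Other probes lay on the opposite side for GOLGB1 (-0.45), SFXN5 (+0.03) and PPA2 (+0.18), at -0.10 for HIF3A and at +0.24 for FBXO11, and averaged +0.06 for LINC00340, +0.09 for BRWD1 and +0.53 for CCDC125. Among other probes of the 51 genes with any, 47.6% of 63 lay on the same side.

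The NPC differences followed the GC content of the probes. Across 20128 genes, which are not independent replicates, Spearman's rho was -0.318 and Pearson's r -0.250, against a rho of 0.029 in EB. The median was +0.10 for 4192 genes with a probe GC of at most 35% and -0.15 for 3127 genes with at least 55%. With this trend removed, WNT pathway targets had a median of -0.29 (percentile 0), the retinoic acid pathway -0.12 (percentile 1.05) and alcohol and aldehyde metabolism -0.02 (percentile 35.8). With normexp correction 13 genes were higher and 64 lower, MLC1 was at -2.61, FGF1 at -1.89, SLC35D3 at 5.10, JUNB at -0.16 and ALDH1A1 at -0.06. The share of higher genes was 36.1%, against 16.9% with normexp, 46.4% after a median shift and 71.3% with spike-in spots.

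**Figure D3:**
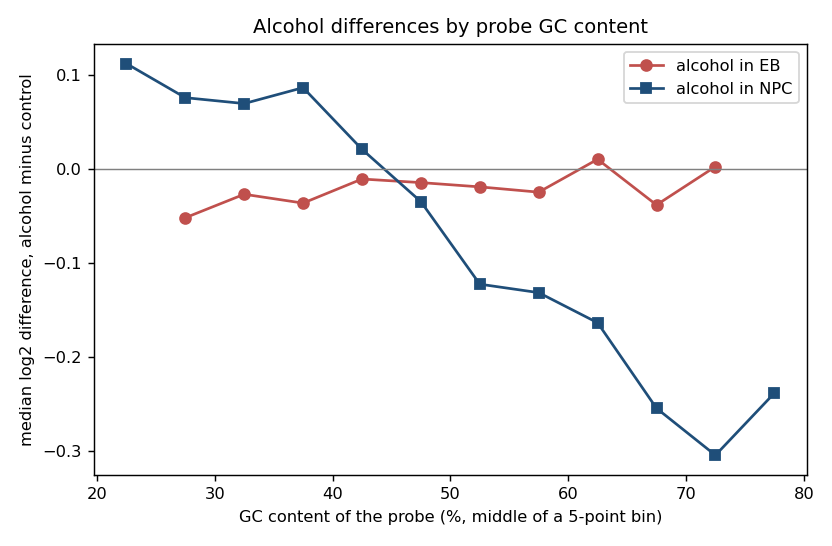
Median log2 difference between the alcohol and the control array (y axis) for genes grouped by the GC content of their probe in 5-point bins (x axis, percent), circles for EB and squares for NPC. The NPC medians run from above 0 at low GC to below 0 at high GC (rho -0.318 across genes), and the EB medians stay near 0 (rho 0.029).

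Without alcohol, the NPC array differed from the EB array by higher neuronal and neural progenitor genes and lower epithelial, hypoxia, mesoderm, endoderm and pluripotency genes, relative to all genes. This comparison sets 1 NPC array against 1 EB array. The NPC titles carry the tag CHIR and not the tag H9 of the EB titles. A difference of cell line or culture therefore cannot be told apart from the stage. Of 36 measured neuronal differentiation genes 34 were higher in NPC, with a median of +2.52 log2 (percentile 100). They included STMN4 (+7.21), a microtubule regulator, the proneural factor NEUROG1 (+5.16), the growth cone protein GAP43 (+5.10) and doublecortin DCX (+4.78), with GAD1 at -4.61. Neural progenitor genes had 21 of 28 higher (median +1.08, percentile 100), led by the neural transcription factor PAX6 (+4.10) and the Notch effector HES5 (+3.09), then SOX3 (+2.51), with ZIC2 at -2.30. Oxidative phosphorylation had a median of +0.49 (percentile 99.8), and forebrain patterning +0.59 (percentile 99.1; -0.43 with bounds).

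Markers of other lineages were lower in NPC relative to all genes. On the spike-in scale 9 of 17 pluripotency, 9 of 15 mesoderm and 17 of 27 adhesion genes were higher, with medians of +0.17, +0.08 and +0.32 against +1.17 for all genes. Surface ectoderm and epithelium had 11 of 12 members lower (median -3.61, percentile 0), among them KRT19 (-11.68), CLDN4 (-9.56) and KRT18 (-6.11). Hypoxia and glycolysis had 29 of 32 lower (median -1.76, percentile 0), with the peptide hormone gene ADM at -9.54, NDRG1 at -5.25 and LOX at -4.70. Pluripotency genes had 14 of 17 lower (median -1.19, percentile 0.14, but 5.3 with the mean over probes) and another 11 that were well above background in EB alone, which put the median with bounds at -2.80. EPCAM was at -6.76 and POU5F1 at -5.50. The medians were -2.20 for neural crest (percentile 0.05), -1.59 for endoderm (0.94), -1.28 for mesoderm (0.71, but 37.0 with a stricter filter) and -1.03 for cell adhesion and extracellular matrix (0.02). Within these, the crest factors SNAI2 and FOXD3 were at -3.68 and -3.65, collagen COL1A1 at -7.32 and TNC at -6.61, with the axonal adhesion protein CNTN2 at +5.55.

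Of 18898 genes well above background on both control arrays, 2807 were at least 2-fold higher and 4803 at least 2-fold lower in NPC. By the same rule for named genes, among the highest were STMN4 (148-fold; chromosome 8 at 27094189 to 27094248), the hormone gene TRH (54.2-fold), CNTN2 (46.8-fold), TTC9B (44.1-fold) and PRDM12 (42.9-fold). PRDM13 (36.0-fold, and +0.51 log2 by its other probe), NEUROG1 (35.6-fold), GAP43 (34.4-fold) and RHBDL3 (32.7-fold) were also among them. The lowest by this rule were KRT19 (3282-fold; chromosome 17 at 39679918 to 39679977), the serine protease PRSS8 (930-fold), BST2 (758-fold), CLDN4 (757-fold; chromosome 7 at 73246907 to 73246966) and ADM (743-fold). The tight junction gene CLDN3 (374-fold), TGFBI (341-fold), the lactate transporter SLC16A3 (287-fold), EGR2 (247-fold) and FER1L4 (233-fold) followed. Several of these were dim in NPC: KRT19 was at -5.06 on the NPC control array, near its floor of -5.64. With normexp correction KRT19 was at -8.66 log2, PRSS8 at -7.16, CLDN4 at -7.68 and ADM at -6.98. By the same correction SLC16A3, brighter in NPC, was at -7.56 and STMN4 at +6.02. The largest bounds were SHISA3 (at least 97.2-fold), BHLHE22 (at least 72.8-fold) and ANKRD20A8P (at least 41.0-fold by 1 probe, +3.04 log2 by its other) higher, and MIR205HG (at least 2487-fold), CDH1 (at least 1647-fold) and HAPLN1 (at least 1621-fold) lower. Other probes of these genes lay on the same side for 78.4% of 2010. The share of higher genes depended on the scaling: it was 36.9%, against 48.9% with quantile normalization, 75.3% after a median shift and 88.7% with spike-in spots.

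**Figure D4:**
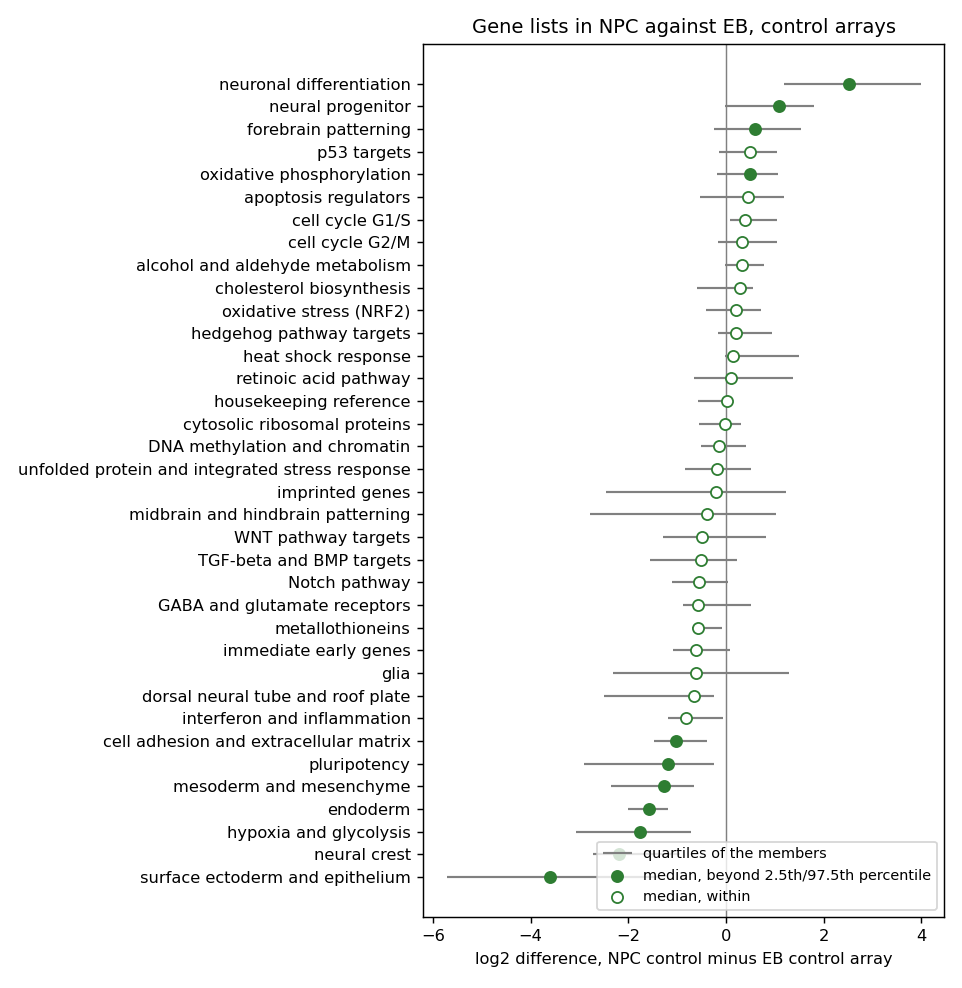
Log2 difference between the NPC and the EB control array (x axis) for 36 gene lists (y axis); the circle is the median of the measured members, the line runs between their quartiles, and filled circles lie in the outer 2.5% of random lists on either side. Neuronal differentiation stands highest at +2.52 and surface ectoderm and epithelium lowest at -3.61.

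The alcohol differences of the 2 stages had little in common across genes. Over 18300 genes well above background on all 4 arrays, which are not independent replicates, Pearson's r was 0.066 and Spearman's rho 0.067, and 52.0% had the same sign. At least 2-fold higher in both stages were 7 genes, against 1.18 for independent lists of these sizes, and 5 genes were lower in both, against 1.33. Another 10 were higher in EB and lower in NPC, against 2.59, and 0 the other way round, against 0.606. By the smaller of their 2 differences, leading genes included the pseudogene OR7E5P (+1.24), FAM160A1 (+1.16), SNORD74 (+1.15, by a probe named for a small nucleolar RNA) and LINC00340 (+1.01). The other probe of FAM160A1 was on the same side in EB (+1.43) and at -0.12 in NPC, and both other probes of LINC00340 lay on the opposite side in EB (mean -0.49). On the lower side were SERINC2 (-1.47), the lens crystallin CRYBB1 (-1.03), DDX11L10 (-0.84), S100A5 (-0.82) and MAB21L2 (-0.78). With normexp correction no gene was at least 2-fold higher in both stages or lower in both, and SERINC2 was at -0.97 in EB and -0.56 in NPC.

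The difference between the responses, NPC minus EB, was at least 2-fold for 807 genes, 302 higher and 505 lower, as values without a test. The number depended on the processing: it was 225 with normexp and quantile, 1325 in the authors' value table and 2459 with spike-in spots. Relative to all genes, surface ectoderm and epithelium (median -0.58, percentile 0), immediate early genes (-0.36, percentile 0.01), hypoxia and glycolysis (-0.32, percentile 0) and WNT targets (-0.31, percentile 0.04) had lower responses in NPC than in EB. Only 11 of 22 epithelial genes were measured on all 4 arrays, with 9 lower and 2 higher, and KRT18 was at +0.75. Epithelial and hypoxia genes were also dimmer on the NPC control array than on the EB one (medians -3.61 and -1.76 log2). Whether this lowers their responses in NPC was not tested. On the spike-in scale the median of all genes was -0.30 for alcohol in EB and +0.28 in NPC. The signs of the list medians of the difference in response therefore depend on the scaling. Neural crest was at -0.45 (percentile 0.72). Higher in NPC were the responses of G1/S genes (+0.23, percentile 99.97), cholesterol biosynthesis (+0.22, percentile 99.87) and G2/M genes (+0.19, percentile 99.5, and 97.0 with the probe GC trend removed). Single genes with the largest differences were NSMCE1 (+5.11), the probes named for the small nucleolar RNAs SNORA28 (+4.05) and SNORD26 (+3.29), BBS7 (+3.17) and PHYHIP (+3.09). On the other side were MLC1 (-5.24), ISCA1 (-4.73), IL1RAPL1 (-4.67), the integrin ITGA8 (-3.85) and SIGLEC15 (-3.64).

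**Figure D5:**
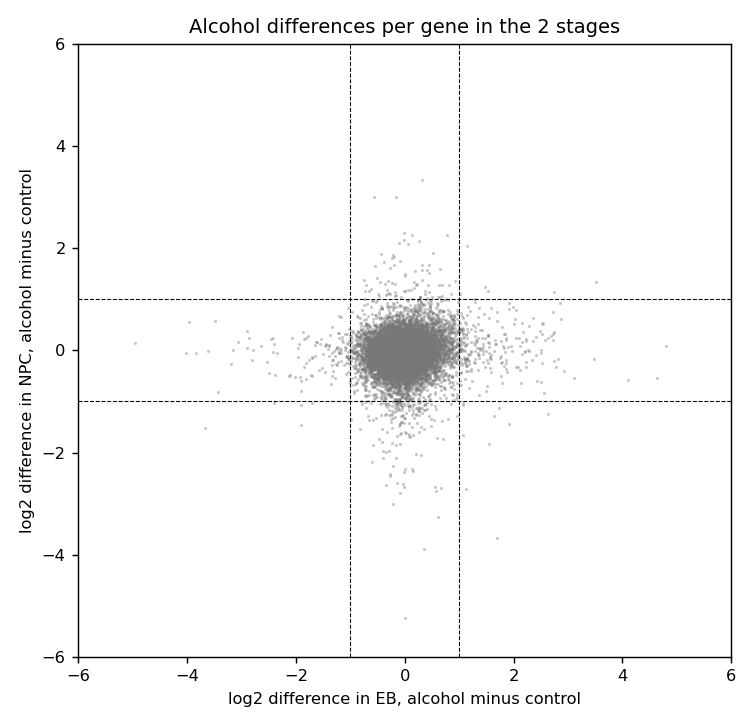
Log2 difference between the alcohol and the control array in EB (x axis) and in NPC (y axis) for 18300 genes well above background on all 4 arrays; each point is a gene and dashed lines mark 2-fold. Pearson's r across genes is 0.066, with 7 genes beyond the lines in the upper right and 5 in the lower left.

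A response alike in both stages was tested with limma over all 4 arrays, with the stage as a covariate and 1 residual degree of freedom. Of 21920 genes, 0 had a Benjamini-Hochberg adjusted p under 0.05. The smallest adjusted p was 0.0575, and 1342 genes had an unadjusted p under 0.05. Adjusted over the list alone, 2 members of the 36 lists passed, both named after their values were seen. Both fits rest in part on values not well above background, so their p values are not read as a test of a shared response. The hindbrain patterning gene HOXD3 (adjusted p 0.00499 over its list and 0.175 over all genes) was well above background on both alcohol arrays and on neither control array, so its folds are bounds: at least 2.93-fold higher in EB and at least 3.55-fold in NPC. HAND1 (0.0179 over its list and 0.316 over all genes) was not well above background on either NPC array, so only its EB difference, given above, can be read.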

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

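The test of other probes in this part was chosen only after the result was seen. Of 10 genes at least 2-fold higher with alcohol in EB and at least 2-fold lower in NPC, the 5 with a gene symbol were marked; the difference between the stages has 1 array on each side and was not tested. ITGA8, an integrin subunit, was at +1.12 in EB and -2.72 in NPC, a difference of -3.85 log2. XRRA1 was at +1.56 and -1.84 (-3.39), and its other probe lay on the same side in both stages. C3AR1, the complement C3a receptor, was at +1.91 and -1.45 (-3.36). FAM186B was at +1.64 and -1.29 (-2.93). CYP1B1, a cytochrome P450 enzyme, was at +1.07 and -1.02 (-2.10), and its other probe lay on the same side in EB only.

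The genes at least 2-fold apart with alcohol were weighed as a pattern, since 412 higher and 171 lower genes in EB and 150 and 265 in NPC passed the rule of size without a replicate. For the 70 genes in EB and 51 in NPC that had other probes, the tables argue against a response that these probes share. Of the other probes 52.2% lay on the same side in EB and 47.6% in NPC, against 78.4% for the stages. For genes under 2-fold these shares were 59.0% in EB and 61.7% in NPC. Most genes had no other probe and could not be read this way. The tables also argue against the probe GC trend as the source of most of these genes in NPC, since 89.4% of the number was left after its removal. The trend was small beside the 2-fold rule, as its removal took the SD of the NPC differences from 0.366 to 0.355 log2. The error of single spots remains a candidate explanation for part of these genes: among probes printed 10 times, 2.27% were at least 2-fold apart in EB by 1 drawn spot and 0.849% by the mean of 10, and 1.19% and 0% in NPC. A response of some of the genes to alcohol, or a difference between the cultures, stays open and was not tested.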

How the results depend on the processing

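No value has a replicate, so leaving out an array was not possible. No paired analysis was possible because each group holds 1 array, so no numbers pair them; the limma model compares alcohol with control within each stage. The shift to spike-in spots, the removed probe GC trend and the every-probe rule were chosen after seeing the data; the cause of the moves below was not tested except where the setting's construction gives it. Counts kept within 1.5 times of the main ones, for all counts run, with quantile normalization, the mean over probes, outlier spots kept, the GC trend removed and the alcohol arrays for the stages (2895 higher and 5006 lower). All limma alternatives also called 0 genes, with 32 (no stage term) to 1358 (no filter) at an unadjusted p under 0.05. Of medians, relative to all genes, of lists that stood apart, 335 moved by less than 1 SD of random medians, 57 by more, and 1 reversed: alcohol and aldehyde metabolism in NPC was at 0.0131 in the authors' table. The 335 include 40 with the median shift and 40 with the spike-in shift, which move every gene alike and could not move these medians. Of values of named genes, 228 moved by less than the spot spread, 278 by more and 0 reversed. With normexp a reversal was excluded in advance, since the rule for named genes asked for the same side there. The stricter filter kept the main values, so its 26 entries among the 228 could not move. The median shift and the spike-in shift were smaller than the differences of the named genes, so they could not reverse one either.

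Normexp and quantile gave 187 higher and 52 lower in EB, 13 and 64 in NPC, 2539 lower between the stages, 0 and 0 in both stages and 225 with different responses; all 187 and 52 were among the main EB genes. The median shift gave 6962 higher and 2285 lower between the stages and 3 lower in both stages. The authors' table gave 413 lower in EB, 288 higher in NPC, 12 higher and 23 lower in both stages and 1325 with different responses. With no filter, where dim genes enter, the counts were 2167 and 1930 in EB, 1723 and 1969 in NPC, 16756 lower between the stages, 268 and 191 in both and 6945 with different responses. The stricter filter left 9150 genes, with 50 and 3 in EB, 6 and 43 in NPC, 1445 and 1521 between the stages, 1 and 1 in both and 107 with different responses. A 1.5-fold rule gave 1158 and 903, 576 and 916, 4759 higher between the stages, 85 and 55 in both and 2862 with different responses, and a 3-fold rule 202 and 79, 50 and 84, 1148 and 2750, 0 and 0, and 248. Spike-in spots gave 474 lower in EB, 348 and 140 in NPC, 10486 and 1331 between the stages, 14 higher in both and 2459 with different responses; they moved the median of all genes to -0.30 in EB, +0.28 in NPC and +1.17 between the stages, and the median shift to +0.60 between the stages. The every-probe rule gave 6 and 1 of 4400 genes in EB, 1 and 1 of 4894 in NPC, and 236 and 376 of 4282 between the stages. Signal over background limits the dim genes most, where spots differed by 0.17 log2 in EB.

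The EB medians of epithelium, hypoxia, immediate early, adhesion, imprinted, neural crest, G1/S, G2/M and cholesterol genes stayed beyond the same percentile in all settings run for them (9 or 10), as did WNT targets in NPC. The settings counted here include the median shift and the spike-in shift, which could not change a percentile. Retinoic acid genes in NPC came inside with no filter and with the stricter one, and alcohol and aldehyde metabolism under 6 of 10 settings. In EB, neural progenitor genes came inside under 4 of 10 settings, forebrain genes with the mean over probes and metallothioneins with the stricter filter. Between the stages, pluripotency genes did so with the mean over probes and mesoderm genes with the stricter filter.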

Other observations

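The test of the main cell type's share, the probe GC test of the EB lists and the single-spot test of WNT targets were chosen only after the result was seen, and the rule that all probes of a gene pass was added after seeing the data. Genes whose probes all differed at least 2-fold are few, and are named here although the rule for named genes did not pick all of them. In EB with alcohol, POU5F1 was higher by at least 1.15 log2 over 2 probes, although near-identical copies of this gene could add to its signal, under the every-probe rule that left 6 higher genes. FAM160A1 (at least 1.43) and the purinergic receptor P2RY1 (at least 1.01) were higher too, and RNF207 was lower (at least -1.02). In NPC with alcohol, KRT18 was higher over 2 probes (at least 1.11), and others higher by every probe included ANXA2, a membrane-binding protein, at 0.85 and the growth factor FGF2 at 0.75, both under 2-fold by their smaller probe.

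Between the stages, several lists that did not stand apart from random lists held large single differences. TGF-beta and BMP targets had a median of -0.50 with TGFBI at -8.41. Imprinted genes had a median of -0.21 with PHLDA2 at -5.68, and midbrain and hindbrain genes a median of -0.39 with FGF8 at -5.13. In NPC with alcohol, hedgehog targets were at percentile 96.4, oxidative phosphorylation at 97.3 and glial genes at 66.9, with MLC1 at -5.25 and CD44 at +0.98.

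The EB lists moved in a way that a biologist may want to follow up: epithelial, hypoxia and immediate early genes higher, cell cycle and cholesterol genes lower. The tables argue against the probe GC trend, since the fitted trend over the members of the 6 leading lists amounted to at most 1.92% of the list median. Markers of other lineages did not all lie high. Endoderm markers lay at percentile 36.1, on 12 of 24 members, and neuronal differentiation genes at 46.2, beside epithelium at 100. These percentiles were known when the test of the main cell type's share was set, and that cell type was not identified. The test therefore decides nothing about a lower share of the main cell type. A change in the share of 1 other cell type need not raise every list, so such a change in cell mix stays open. A difference between the cultures or arrays other than alcohol cannot be told apart from alcohol, with 1 array per group. A response to alcohol stays open as an untested hypothesis.

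WNT targets were lower with alcohol in NPC, relative to all genes. The probe GC trend seen in NPC is argued against, since with it removed the list lay at percentile 0. Independent error of single spots, which random lists of the same brightness carry too, is argued against as the whole cause, since the list lay at percentile 0.02 or lower in every setting. Of the other probes of the targets 83.3% lay lower, but these are only 6. Both NPC titles carry the unexplained tag CHIR, and the sources used here do not say whether the cultures held an added WNT activator. A culture or array difference other than alcohol cannot be told apart from alcohol with 1 array per group, and a lower WNT response with alcohol remains a hypothesis that was not tested.

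HOXD3, well above background on both alcohol arrays and on neither control array, prompted a count of such genes. There were 122, against 69 on both control arrays alone and a mean of 82.5 for the 2 crossed pairs (91 for EB alcohol with NPC control, 74 for EB control with NPC alcohol). The ratio of 1.48 lay just under the bound of 1.5 set before counting, so chance at the detection limit was not argued against.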
